A study of Mus musculus with 18 samples.

How the data were processed

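Small RNA was sequenced from the livers of wild-type C57BL/6J mice, an inbred laboratory strain, in 18 libraries that fall into 6 groups of 3. Mice were on their regimens from 5 weeks of age and were sampled at 62 weeks. The group names in the labels are LF, LF+CR, LF+Ex, HF, HF+CR and HF+Ex. The labels do not spell these out; LF and HF are read here as low-fat and high-fat diet, CR as calorie restriction and Ex as exercise. Per the labels' protocols, frozen livers were extracted with Trizol, total RNA was enriched for small RNA, and libraries were made with standard Illumina chemistry. Groups and replicate numbers came from the sample titles. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values here measure only the spread between these samples, which may be technical.

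The deposited values are RPM, reads scaled to the library total, for 758 mature mouse miRNAs, per the file headers. The values of the per-sample tables and of the series table were the same, with a largest difference of 0 RPM. The genome build is mm10, per the submitters' processing notes. The aligner, the counting tool, the miRNA annotation release and any filter are not given in the sources used here, nor is the handling of reads that match several miRNAs. RPM is a share of a library's reads, so a change in abundant miRNAs moves the others, and a fold is relative to the whole library. The deposited RPM columns summed to between 963787.9 and 971206.7, so listed miRNAs made up 96.4% to 97.1% of the RPM scale.

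Depth was read from the RPM steps. In each library all values (100%, tolerance 0.001 reads) were whole multiples of a single step, taken as the RPM of 1 read, and the smallest listed value was 2 reads; a listed 0 can thus stand for 0 reads or 1 read. Reads on listed miRNAs, in megareads (M), ranged from 2.38 M (HF+Ex 1) to 10.5 M (LF+Ex 2). The group means were 7.78 ± 0.988 M for LF, 6.33 ± 1.30 M for LF+CR and 8.54 ± 1.74 M for LF+Ex (SD, n = 3). They were 5.56 ± 1.31 M for HF, 3.95 ± 1.37 M for HF+CR and 6.11 ± 3.31 M for HF+Ex. These reads carry no molecular identifiers and are not independent molecules.

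Tests ran on log2(RPM + 1) for the 351 miRNAs with an RPM of at least 5 in at least 3 of the 18 libraries; the other 407 were not tested. A fold change is on that scale, where the pseudocount of 1 RPM understates the change of low miRNAs. Each comparison used limma 3.58.1 in R 4.3.3 with all 18 libraries in 1 fit and 1 coefficient per group (lmFit, contrasts.fit, eBayes with an intensity trend and without robust weights), two-sided, with Benjamini-Hochberg adjustment over the 351 miRNAs. A miRNA was called at an adjusted p under 0.05. Sharing the fit lets each group of 3 borrow its spread from all groups. The 9 comparisons were HF against LF, CR and Ex against their control on each diet, CR and Ex averaged over both diets, and the difference between diets of the CR effect and of the Ex effect (HF minus LF). Tables were read with jsonlite 2.0.0 and plotted with matplotlib 3.10.9 in Python 3.11.15.

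The comparisons, tests, filter, pseudocount, 22 miRNA lists, most alternatives and the rule for named miRNAs were set before the data were examined. The rule names, per comparison, up to 12 called miRNAs with the largest increase and up to 12 with the largest decrease; where fewer than 5 were called, it adds those with the smallest p to make 6. It also admits members of the fixed lists, and the 10 miRNAs with the highest mean RPM. The stated design left open whether the intensity trend was on, so a fit without the trend was added as an alternative. Other alternatives chosen after seeing the data were limma's voom weights on the reads implied by the RPM steps, counting miRNAs with identical values once, and leaving out pairs or sets of libraries with high pancreatic, neuronal, or leukocyte and epithelial miRNAs or with the least depth. The alternatives set earlier were a pseudocount of 5, no filter, a filter of 50 RPM, RPM rescaled by median-of-ratios size factors, only the compared groups in the fit, the replicate number as a block, and leaving out each library in turn.

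Each list was tested with limma's camera, which asks whether its members rank higher or lower than the other miRNAs, with a preset correlation of 0.01. Adjustment covered 189 tests, 21 lists by 9 comparisons; the muscle list had 2 measured members, under the minimum of 3, and was not tested. With a correlation estimated from the data none of the 23 camera calls held, so each call given has that second p. The Sfmbt2 list had 2 distinct measurements among its 7 members, which camera counts as 7; its 4 calls rest on that and are not read as list results. With identical miRNAs counted once that list falls under the minimum, and 20 calls were made. Counts of list members past the test are given over all miRNAs tested and adjusted over the list alone. Many miRNAs stand on several lists, and all members tested here passed an expression filter in liver.

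Precursor coordinates are from GENCODE vM21 on GRCm38, the assembly also called mm10, matched by name for 331 of the 351 tested miRNAs; 304 had 1 precursor gene and 27 had several, so that the copy of origin is not known. Among tested miRNAs, 3 sets with 9 members had identical values in every library and cannot be told apart: let-7a-1-3p with let-7c-2-3p, 5 miR-466 forms, and miR-669a-3p with miR-669o-3p. Near-identical family members can share reads depending on the counting, and overlapping genes likewise.

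The fit and camera were tested on simulated data: 20 sets over the 351 miRNAs, with 14 miRNAs changed at each fold size. Each miRNA was drawn with the spread that the main fit had estimated for it, the same in every library. The share of calls that were unchanged miRNAs is thus no separate test of those spreads. For LF+CR against LF, 16.1% of the miRNAs changed 1.5-fold were recovered, 48.9% at 2-fold and 83.9% at 4-fold, and 4.06% of calls were unchanged miRNAs. For CR averaged over diets recovery was 38.6%, 74.6% and 94.3%, with 4.34% of calls unchanged. For the difference between diets of the CR effect it was 2.86%, 21.8% and 67.5%, with 3.83% unchanged. A planted list of 12, with the same shift in all members, was found in 20 of 20 sets and an unchanged list in 0 of 20. The simulated miRNAs were drawn independently of each other, without a shift in library composition and without single libraries that stand apart. These shares therefore do not measure errors from correlated miRNAs, from such a shift or from such libraries. Replicates within groups had r of 0.953 to 0.994 on the log2 scale.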

Results

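Liver small RNA was profiled in 6 groups of 3 libraries, with LF or HF diet alone, with CR or with Ex. The profile was that of hepatocytes: miR-122-5p, the most abundant liver miRNA, took 25.5% of the listed RPM on average. It was followed by miR-21a-5p at 8.63%, miR-29a-3p at 6.60%, and miR-194-5p and miR-192-5p at 5.45% and 3.35%. The miRNAs let-7f-5p, miR-29c-3p, let-7a-5p, miR-30a-5p and miR-101b-3p completed the 10 most abundant, with mean levels between 31447 and 23743 RPM over the 18 libraries. Between 476 and 608 of the 758 miRNAs were listed above 0 in a library. The first principal component held 32.1% of the variance and the second 15.7%.

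**Figure D1:**
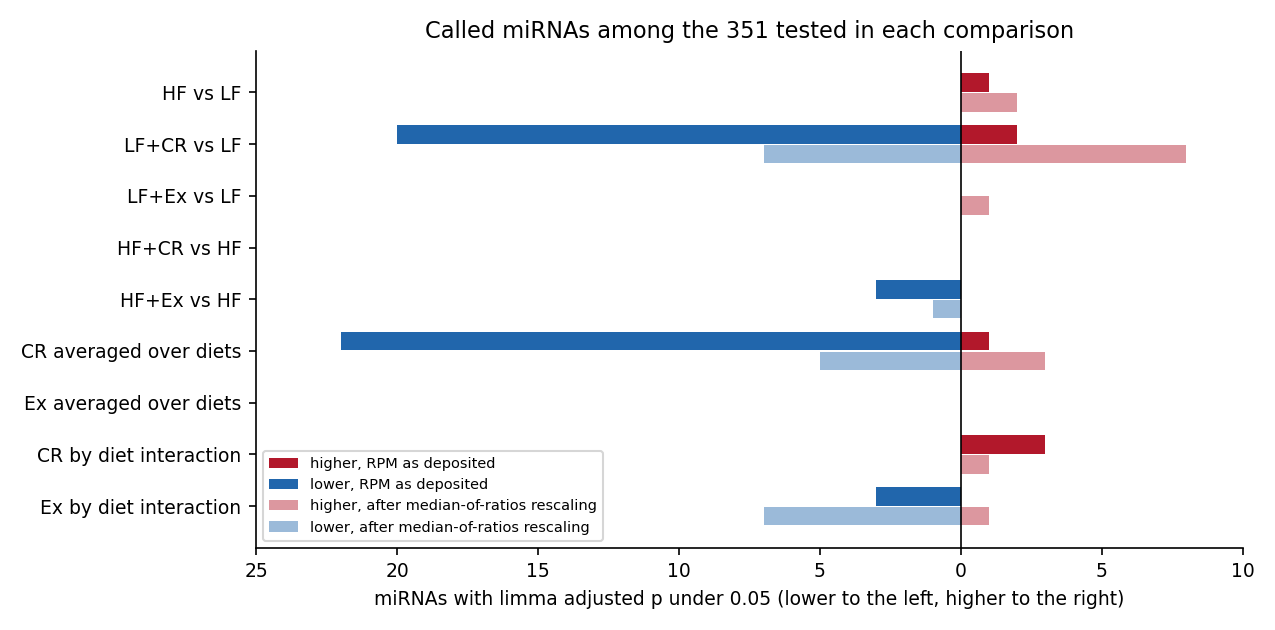
Bars give the number of the 351 tested miRNAs called by limma (adjusted p under 0.05) in each comparison, lower to the left and higher to the right, with RPM as deposited (solid) and after median-of-ratios rescaling (pale). LF+CR against LF had 20 lower and 2 higher as deposited, and 7 lower and 8 higher after rescaling.

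The effect of the HF diet was read from HF against LF. miR-33-5p, which lies in an intron of the sterol regulator gene Srebf2 and represses cholesterol export genes, was higher: 19.5 ± 5.67 RPM in HF and 5.69 ± 0.613 RPM in LF (SD, n = 3). The log2 fold change was 1.58 (SE 0.26, adjusted p = 0.00715), and 3 of 3 HF libraries lay above every LF library. miR-33-5p was picked for a small p in the same libraries, so this separation adds no support. Its precursor Mir33 is at chromosome 15, 82198122 to 82198190, plus strand (GRCm38). It was the only miRNA called of 351, although 41 had an unadjusted p under 0.05, where chance gives 17.55, and 67 showed no overlap between groups, where chance gives 10%. Not past the test were the cell cycle regulator miR-503-5p at 0.86 (adjusted p = 0.166), the hypoxia-induced miR-210-3p at 0.91 (adjusted p = 0.166), let-7e-5p at -1.12, miR-32-5p at 0.84 and miR-450a-5p at 0.67 (adjusted p = 0.307 for all 3). miR-34a-5p, a p53 target often raised in fatty liver, was at 2700 ± 490 RPM in HF and 2206 ± 1147 RPM in LF, a difference within the spread. The miR-33-5p call was lost without LF 2 (adjusted p = 0.0517), HF 2 (0.0611) or HF 3 (0.0783), over a range of 0.00249 to 0.105 across its alternatives; without HF 1, 2 miRNAs were called. Without LF 1 and HF+CR 3, a pair of libraries high in leukocyte and epithelial miRNAs, 7 miRNAs were called, all higher.

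In the fixed lists for the same comparison, 1 of 25 members of the lipid and sterol list was higher (miR-33-5p) and none lower, also when adjusted over the list alone; the list as a whole did not pass (adjusted p = 0.633). The 12 measured members of the Dlk1-Dio3 imprinted cluster, a large cluster on chromosome 12 expressed from the maternal copy, all had values below 0 (median -0.70), among them miR-379-5p at -1.07 and miR-411-5p at -1.09. The epithelial miR-200 family was below 0 too, in 5 of 5 (median -0.59; camera adjusted p = 0.273), and the epithelial-high LF 1 held 233 RPM of the cluster, against 74.5 and 144 RPM in LF 2 and LF 3. No cluster member passed singly, over all miRNAs or adjusted over the list alone; camera placed the list below the others (adjusted p = 7.14e-04; adjusted p = 0.948 with an estimated correlation). The cluster of miR-183-5p, miR-96-5p and miR-182-5p, first known from sensory organs, had 3 of 3 members below 0 (median -1.04), with miR-182-5p at 68.9 ± 19.8 RPM in HF and 237 ± 216 RPM in LF; 1 of 3 was lower adjusted over the list alone. Its camera adjusted p was 0.0254 (adjusted p = 0.948 with an estimated correlation), and the call was lost without LF 1 (0.223), whose miR-182-5p was 486 RPM, or without HF 1 (0.106). For the let-7 family, regulators of growth and glucose metabolism, 12 of 16 members were below 0 (median -0.17) and none passed; camera gave 0.0254 (adjusted p = 0.948 with an estimated correlation), lost without LF 2 (0.111) or HF 3 (0.0681). Leukocyte and Kupffer cell miRNAs had a median of 0.67 with 9 of 11 above 0, and did not pass (adjusted p = 0.112). Fragment-like entries, a list meant as an RNA quality check, had a median of 0.86 with 4 of 4 above 0 and did not pass either. They summed to 54.7, 58.9 and 169 RPM in HF and to 37.6 to 44.1 RPM in LF, so RNA quality was not separated from an effect of the diet.

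The effect of CR on the LF diet was read from LF+CR against LF, where 2 miRNAs rose and 20 fell. The largest decreases were those of miR-34a-5p, from 2206 ± 1147 to 557 ± 226 RPM (log2 fold change -1.93, SE 0.50, adjusted p = 0.0298), and of miR-669a-3p and miR-669o-3p, from 11.1 ± 5.28 to 2.16 ± 0.759 RPM (-1.88, SE 0.41, adjusted p = 0.0164; SD, n = 3). Both arms of miR-1948, an intronic miRNA of Ttc39c, fell: the 3p arm from 57.6 ± 19.4 to 17.2 ± 3.52 RPM (-1.66, SE 0.25, adjusted p = 0.00225) and the 5p arm by 1.49 on the log2 scale. miR-574-5p (-1.65, SE 0.31), miR-328-3p (-1.46, SE 0.31), miR-148b-3p (-1.01, SE 0.26), miR-1198-5p (-0.94, SE 0.22) and miR-671-5p (-0.83, SE 0.15) fell too, with adjusted p between 0.00886 and 0.0289. Higher were miR-33-5p, from 5.69 ± 0.613 to 12.9 ± 3.64 RPM (1.03, SE 0.26, adjusted p = 0.0289), and miR-29a-3p, a repressor of collagen genes, from 55495 ± 3938 to 81127 ± 10003 RPM (0.54, SE 0.13, adjusted p = 0.0180). Several of these calls rest on single libraries. With 1 of the 6 libraries left out, that of miR-33-5p was kept in 1 of 6 (adjusted p 0.0149 to 0.220 across its alternatives), that of miR-34a-5p in 2 (0.00864 to 0.208), that of miR-148b-3p in 2 (0.00735 to 0.208), that of miR-1198-5p in 2 (0.00909 to 0.162) and that of miR-29a-3p in 3 (0.00483 to 0.117). Those of miR-1948-3p, miR-671-5p and miR-574-5p were kept in all 6, that of miR-328-3p in 5, and those of miR-1948-5p and the miR-669 pair in 4. For each miRNA named here as called, 3 of 3 LF+CR libraries lay outside the range of LF. These miRNAs were picked for a small p in the same libraries, so this adds no support. The other 8 calls, all lower and between -0.64 and -0.77, were miR-27b-3p, miR-128-3p, miR-98-5p, let-7c-5p, let-7d-5p, miR-1839-5p, miR-423-3p and miR-674-5p; let-7b-5p and let-7d-3p are given with their family. At an unadjusted p under 0.05 there were 101 miRNAs, 90 of them lower, and 101 showed no overlap between groups, where chance gives 10%.

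Lists of other cell types differed in direction here and none of them passed: leukocyte and Kupffer cell miRNAs had a median of -0.59 with 10 of 11 below 0 (-0.29 after rescaling; camera adjusted p = 0.633), erythroid miRNAs -0.61 (-0.33 after rescaling; adjusted p = 0.861), endothelial miRNAs -0.13 (0.20 after rescaling) and pancreatic miRNAs 0.37. Neuronal miRNAs had a median of -0.68 with 6 of 7 below 0 (-0.34 after rescaling), and summed to 521 to 734 RPM in LF and 351 to 402 RPM in LF+CR. Fragment-like entries had a median of 0.55 with 3 of 4 above 0, and summed to 37.6 to 44.1 RPM in LF and 46.6 to 63.8 RPM in LF+CR. The leukocyte list summed to 8694 RPM in LF 1 and to 2909 and 4454 RPM in the other LF libraries. A change in cell content or RNA quality was thus not separated from an effect of CR.

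The median over all 351 miRNAs was -0.32 in this comparison, with 75.2% below 0; it was -0.18 without LF 1, with 66.1% below 0, and -0.43 without LF 2. Rescaling by size factors moved it by 0.33 on the log2 scale and left 15 calls, 8 higher and 7 lower, of which 9 were among the 22. Relative to the other miRNAs miR-33-5p was then at 1.34, miR-29a-3p at 0.88, miR-34a-5p at -1.59 and miR-1948-3p at -1.34. Rescaling ended the limma calls of miR-671-5p (-0.49, adjusted p = 0.165), miR-148b-3p (-0.67, adjusted p = 0.0648) and miR-1948-5p (-1.23, adjusted p = 0.0818), among others. The count was 9 without LF 1, 30 without LF 2, 11 without LF 3, 5 without LF+CR 1, 5 without LF+CR 2 and 40 without LF+CR 3, and 0 with the compared groups alone in the fit. Without LF+CR 1 and HF+CR 1, which held high pancreatic miRNAs, 5 miRNAs were called, all of them among the 22. Without LF 2 and HF+CR 2, which held high neuronal miR-124-3p and miR-9-5p, 55 were called, 52 lower, and all 22 were among them.

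Among the lists, 5 of 16 let-7 family members fell (let-7b-5p, let-7c-5p, let-7d-5p, let-7d-3p and miR-98-5p), the same number adjusted over the list alone. let-7b-5p went from 11044 ± 2303 to 5966 ± 1076 RPM (-0.88, SE 0.21, adjusted p = 0.0202), kept in 4 of the 6 omissions (adjusted p 0.00864 to 0.176 across its alternatives). let-7d-3p went from 498 ± 39.3 to 225 ± 75.4 RPM (-1.19, SE 0.32, adjusted p = 0.0357), kept in 1 of the 6 omissions (adjusted p 0.0230 to 0.209 across its alternatives). The family median was -0.38 and, after rescaling, -0.05 with 0 members called; camera gave 0.0395 (adjusted p = 0.948 with an estimated correlation; 0.317 after rescaling). That call was lost without LF 1 (0.0680), LF 2 (0.154), LF+CR 2 (0.108), HF 1 (0.0562) or HF+CR 3 (0.0523). In the miR-29 family 1 of 7 rose, and 3 rose and 1 fell adjusted over the list alone: the 3p arms miR-29c-3p at 0.50 (adjusted p = 0.0521 over all miRNAs) and miR-29b-3p at 0.49 (0.0969) stood beside miR-29a-3p. The family's median was 0.32 (camera adjusted p = 0.0247; adjusted p = 0.642 with an estimated correlation), lost without LF 1 (0.0613) or LF+CR 2 (0.0982). The Sfmbt2 intron cluster, a rodent repeat-derived set on chromosome 2, had 2 of 7 lower and 7 lower adjusted over the list alone, with a median of -1.19. They are 5 miR-466 forms with identical values (1.40 ± 0.833 RPM in LF+CR and 4.63 ± 2.78 RPM in LF for miR-466a-3p) and the identical pair miR-669a-3p and miR-669o-3p. These are 2 distinct measurements, so no list test is read from them. Hepatocyte-enriched miRNAs had 0 of 13 called and a median of 0.21 (camera adjusted p = 0.0138; adjusted p = 0.948 with an estimated correlation; 0.463 without LF 1). The miR-30 family, regulators of hepatobiliary development, had 0 of 11 called and a median of 0.05 (camera adjusted p = 0.0395; adjusted p = 0.642 with an estimated correlation), lost without LF 1 (0.137), LF 3 (0.0635) or LF+CR 2 (0.140).

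The effect of CR on the HF diet was read from HF+CR against HF. No miRNA was called by limma, with 53 at an unadjusted p under 0.05 and 0 by voom weights. The smallest p belonged to miR-1948-3p, at 78.2 ± 17.4 RPM in HF+CR and 38.0 ± 6.22 RPM in HF (1.01, SE 0.25, adjusted p = 0.127; above every HF library in 3 of 3), miR-592-5p (1.97, SE 0.49, adjusted p = 0.127) and miR-107-3p, which targets insulin signalling (-0.74, SE 0.19, adjusted p = 0.127). miR-378b at -0.94, miR-1981-5p at -0.62 and miR-378c at -1.01 followed, and miR-34a-5p was at -1.07 with a range of 596 to 2940 RPM within HF+CR. In the Dlk1-Dio3 cluster 12 of 12 members lay above 0 (median 1.06) and none passed, also adjusted over the list alone: miR-127-3p was at 39.5 ± 15.9 RPM in HF+CR and 15.6 ± 6.37 RPM in HF (1.28), miR-136-5p at 1.32 and miR-411-5p at 1.53. Camera gave 2.84e-06 (adjusted p = 0.948 with an estimated correlation), and 0.153 without the 3 shallowest libraries. The cluster summed to 252 RPM in HF+CR 1 and 268 RPM in HF+CR 3, which stood apart for pancreatic and for leukocyte and epithelial miRNAs, and to 93.8 RPM in HF+CR 2, within the HF range of 50.4 to 119 RPM; the epithelial-high LF 1 held 233 RPM. The miR-200 family was above 0 in 5 of 5 (median 0.69). HF+CR libraries had the lowest mean depth of the groups. The fragment-like entries, which may reflect degraded RNA, summed to 144 to 344 RPM in them and to 54.7, 58.9 and 169 RPM in HF. The largest of these entries was miR-690, with a mean of 74.8 RPM over all libraries, against 19.5 RPM or less for the others. HF+CR 3 had high leukocyte and epithelial miRNAs; without it 22 miRNAs were called, without HF 1 the count was 3, and without HF+CR 2 it was 1. With HF+CR 3 and LF 1 left out, 25 were called (7 higher, 18 lower), and without the 3 shallowest libraries 9.

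Averaged over both diets, 22 miRNAs were lower with CR and 1 was higher. miR-34a-5p (-1.50, SE 0.35, adjusted p = 0.0256), miR-669a-3p and miR-669o-3p (-1.46, SE 0.29, adjusted p = 0.0147), miR-574-5p (-1.08, SE 0.22, adjusted p = 0.0147) and miR-148b-3p (-0.92, SE 0.18, adjusted p = 0.0147) fell most. miR-148b-3p made up 2.07% of the summed RPM of miR-148a-3p, miR-148b-3p and miR-152-3p. That sum was at 0.09 (SE 0.14) here and at 0.26 (SE 0.19) for CR on LF. Reads moved between these near-identical miRNAs stay open for the miR-148b-3p calls, since so small a part cannot show in the sum. miR-185-3p, miR-1839-3p, miR-328-3p, miR-423-5p, miR-137-3p and miR-1843a-3p fell by 0.86 to 0.60, and each of them lost its call after rescaling. The calls of miR-185-3p, miR-328-3p, miR-423-5p and miR-1843a-3p were each kept in 5 of 12 omissions, that of miR-137-3p in 9 and that of miR-1839-3p in 10. miR-328-3p was at -1.46 on LF and -0.78 averaged, so its average rests mostly on LF. Mir1839 and Mir1843a overlap small Cajal body RNA genes in the annotation, so their reads cannot be told apart from those. The insulin and glucose list had 3 of 23 lower: miR-107-3p (-0.60, SE 0.13, adjusted p = 0.0217), from 5450 ± 367 to 4005 ± 363 RPM on LF and from 6816 ± 1356 to 4105 ± 1086 RPM on HF, its near-identical relative miR-103-3p (-0.49), and miR-29b-2-5p (-0.36). After rescaling 0 were lower and 1 higher, and the list median turned from -0.13 to 0.07. miR-103 and miR-107 lie in introns of the pantothenate kinase genes Pank1, Pank2 and Pank3. miR-27b-3p, miR-98-5p, let-7b-5p, miR-1839-5p, miR-1981-5p, miR-423-3p, miR-505-3p and miR-674-5p also fell, by 0.40 to 0.56. miR-592-5p, an exonic miRNA of Grm8, rose (1.22, SE 0.35, adjusted p = 0.0484), a call kept in 9 of its 24 alternatives and in 3 of 12 omissions (adjusted p 0.0206 to 0.169) and lost after rescaling. Of the 22 calls in LF+CR against LF, 12 were among these 23, an overlap built in by the shared LF and LF+CR libraries. Camera placed the Dlk1-Dio3 cluster higher (median 0.41, adjusted p = 0.00246; adjusted p = 0.948 with an estimated correlation; 0.236 without the 3 shallowest libraries). It placed the miR-30 family higher (0.06, adjusted p = 0.0254; adjusted p = 0.642 with an estimated correlation; lost without LF 1, LF+CR 2 or HF+CR 2, at most 0.0825). The Sfmbt2 cluster had a median of -0.70 and 2 of 7 called, the miR-669 pair. Summed RPM of the miR-34 family, the Sfmbt2 cluster and the leukocyte list was in each case highest in LF 1 within LF and in HF+CR 3 within HF+CR. Leukocyte and Kupffer cell miRNAs were below 0 in 11 of 11 for this average. Without LF 1 and HF+CR 3 the calls of miR-34a-5p and the miR-669 pair were kept. A change in cell content was still not separated from an effect of CR.

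The median over all miRNAs for this average was -0.17; rescaling moved it by 0.20 and left 8 calls, 3 higher and 5 lower, with miR-34a-5p (-1.30), miR-148b-3p (-0.72), miR-574-5p (-0.90) and the miR-669 pair (-1.31) among them. No miRNA was called by limma without the pair of libraries high in pancreatic miRNAs (LF+CR 1 and HF+CR 1), none without HF 2, and none with the compared groups alone in the fit. The count was 6 without LF+CR 1, 6 without HF 3, 10 without LF 3, 10 without HF+CR 2, 12 without LF 1, 39 without LF 2 and 78 without HF+CR 3. It was 12 without the neuronal-high pair, 63 without the leukocyte-high and epithelial-high pair, which kept 20 of the 23, and 49 without the 3 shallowest libraries.

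**Figure D2:**
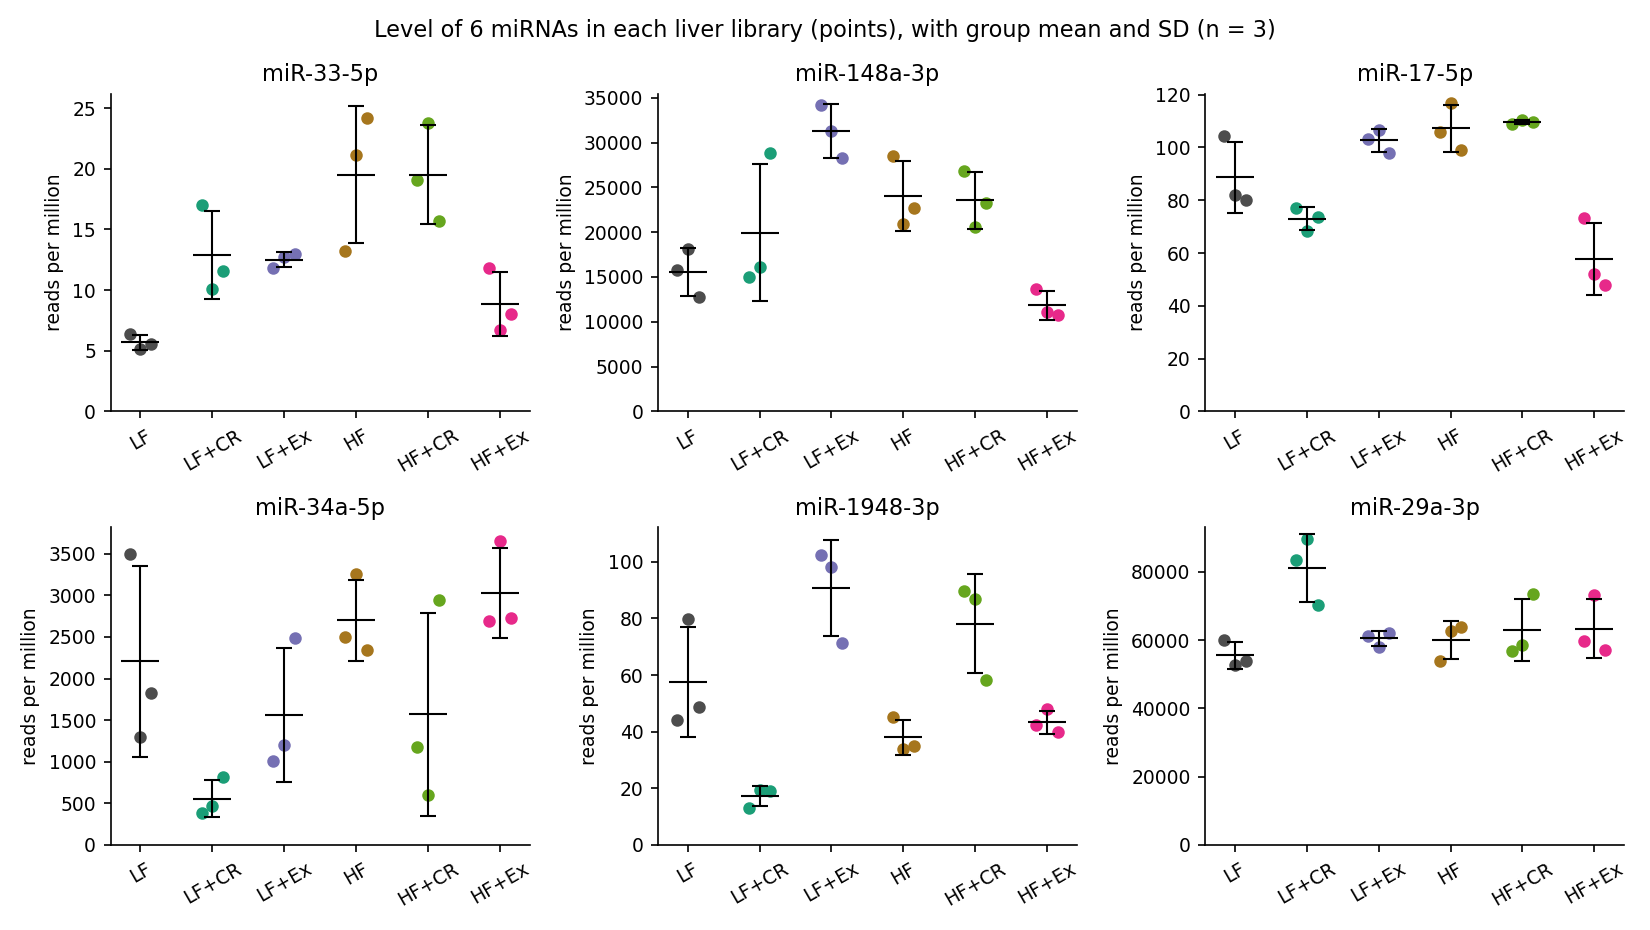
Points are single libraries, horizontal bars group means and whiskers SD (n = 3), on a linear RPM axis from 0. miR-148a-3p stood at 31286 RPM in LF+Ex and 11829 RPM in HF+Ex, and miR-1948-3p at 17.2 RPM in LF+CR and 78.2 RPM in HF+CR.

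The difference of the CR effect between diets (HF minus LF) was past the test for 3 miRNAs, all with a higher value on HF. miR-1948-3p had 3 of 3 LF+CR libraries below LF and 3 of 3 HF+CR libraries above HF, a difference of 2.67 (SE 0.35, adjusted p = 4.82e-04), and miR-1948-5p differed by 2.54 (SE 0.47, adjusted p = 0.0124). The separation of the miR-1948-3p libraries adds no support, since it was picked for a small p in them. Mir1948 lies at chromosome 18, 12714811 to 12714895, plus strand. miR-671-5p, in an exon of Chpf2, was at 57.7 ± 4.60 RPM in LF+CR and 103 ± 5.65 RPM in LF, against 151 ± 27.3 RPM in HF+CR and 131 ± 14.3 RPM in HF (1.02, SE 0.22, adjusted p = 0.0306). Not past it were miR-92a-3p at 1.32 (adjusted p = 0.0794), miR-101c at -1.66 and miR-1247-5p at 1.57 (adjusted p = 0.191 for both). Of the lists, camera placed the Dlk1-Dio3 cluster higher (median 1.29, 12 of 12 above 0, adjusted p = 0.00890; adjusted p = 0.966 with an estimated correlation; miR-411-5p at 2.04), lost without LF+CR 3 (0.0615), HF 2 (0.0543) or the 3 shallowest libraries (0.441). The miR-200 family was above 0 in 5 of 5 (median 0.99; adjusted p = 0.652) and the neuronal list in 7 of 7 (median 0.58; adjusted p = 0.335). Hepatocyte-enriched miRNAs were placed lower (median -0.22, 0 of 13 called and 2 lower adjusted over the list alone: miR-101a-3p at -0.90 and miR-802-3p at -1.27; adjusted p = 0.00599; adjusted p = 0.769 with an estimated correlation), lost without LF 1 (0.148) or HF+CR 3 (0.245). The insulin and glucose list had a median of 0.040 and a mean of -0.09, while camera placed it lower (adjusted p = 0.0117; adjusted p = 0.675 with an estimated correlation; 0.0720 without LF 1 and HF+CR 3 and 0.0604 without the 3 shallowest libraries) and rescaling turned the median to -0.22; 0 of 23 passed. The miR-29 family had a median of -0.37 with 0 of 7 called (camera adjusted p = 0.0138; adjusted p = 0.642 with an estimated correlation; 0.0523 without HF+CR 3).

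Here the median over all miRNAs was 0.28, rescaling moved it by -0.27, and 1 call was left: miR-1948-3p (2.41, adjusted p = 0.0289). The miR-1948-3p call held in all of its 25 alternatives, with adjusted p between 2.13e-04 and 0.0289. miR-671-5p was lost in 12 of its 25 (adjusted p 0.0187 to 0.285), 7 of them with 1 library left out (LF 2, LF 3, LF+CR 1, LF+CR 2, HF 1, HF 3 or HF+CR 1). The count was 5 without LF+CR 3, 1 without HF 3 and 9 without HF+CR 2, and 17 without the neuronal-high pair of LF 2 and HF+CR 2.

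The effect of Ex was read on each diet. On LF no miRNA was called by limma (41 at an unadjusted p under 0.05, 1 called with voom weights). The smallest p was that of miR-148a-3p, an abundant hepatocyte miRNA that targets the LDL receptor: 31286 ± 2994 RPM in LF+Ex and 15531 ± 2686 RPM in LF (1.02, SE 0.22, adjusted p = 0.0843; 3 of 3 above LF). It was called after rescaling (1.20, adjusted p = 0.0482), which moved the median of all miRNAs by 0.17. miR-33-5p was at 12.5 ± 0.607 RPM in LF+Ex (1.02, adjusted p = 0.166), miR-592-5p at 40.8 ± 8.59 against 13.03 ± 9.84 RPM (1.77, adjusted p = 0.200), miR-1247-5p at -1.40 (adjusted p = 0.141), miR-145a-3p at -0.72 and miR-219-5p at 1.03. Without LF 2, 2 miRNAs were called. Hepatocyte-enriched miRNAs (median 0.16, 0 of 13 called, 1 higher adjusted over the list alone: miR-148a-3p) were placed higher by camera (adjusted p = 0.0259; adjusted p = 0.948 with an estimated correlation; 0.803 without LF 1, 0.0870 without LF+Ex 2 and 0.0513 without LF+Ex 3). The Sfmbt2 cluster had a median of -1.18 (0 of 7 called, 5 lower adjusted over the list alone, the identical miR-466 forms). Its sum was highest in the leukocyte-high LF 1 (73.1 RPM, against 27.0 and 35.9 RPM in LF 2 and LF 3), and leukocyte and Kupffer cell miRNAs were below 0 in 11 of 11 (median -0.38).

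On HF, Ex lowered 3 miRNAs. miR-148a-3p fell from 24036 ± 3940 to 11829 ± 1590 RPM (-1.02, SE 0.22, adjusted p = 0.0429). The growth-promoting cluster members miR-17-5p and miR-20a-5p fell from 107 ± 9.01 to 57.7 ± 13.6 RPM (-0.90, SE 0.17, adjusted p = 0.0235) and from 1071 ± 139 to 599 ± 129 RPM (-0.85, SE 0.19, adjusted p = 0.0483). Each of the 3 was below every HF library in 3 of 3. They were picked for a small p in the same libraries, so this adds no support. Of all 351 miRNAs, 63 showed no overlap between these groups, where chance gives 10%. Mir148a is at chromosome 6, 51269812 to 51269910, minus strand, in no annotated gene on that strand, and Mir17 and Mir20a are in exonic sequence of Mir17hg at chromosome 14, 115043671 to 115043754 and 115044157 to 115044263. Not past the test were miR-33-5p at 8.83 ± 2.65 RPM (-1.05, adjusted p = 0.0928), miR-148b-3p at -0.86 (adjusted p = 0.303) and miR-30e-3p at 0.47 (adjusted p = 0.326). The miR-17/92 and paralogous clusters had 2 of 16 lower, also adjusted over the list alone, and a median of -0.26 (camera adjusted p = 0.00890; adjusted p = 0.948 with an estimated correlation). In the let-7 family 14 of 16 were above 0 (median 0.21) and none passed, such as let-7a-5p at 0.42 and let-7d-3p at 0.86 (camera adjusted p = 0.0254; adjusted p = 0.948 with an estimated correlation; 0.0639 without HF 3 and 0.281 without HF+Ex 3). The count was 0 without any of HF 1, HF 2, HF 3, HF+Ex 2 or HF+Ex 3, and 5 without the shallow HF+Ex 1, which also held the highest sum of fragment-like entries (458 RPM, against 40.4 and 55.2 RPM in HF+Ex 2 and HF+Ex 3). It was 1 with no filter, with rescaling, with the compared groups alone and with no intensity trend.

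**Figure D3:**
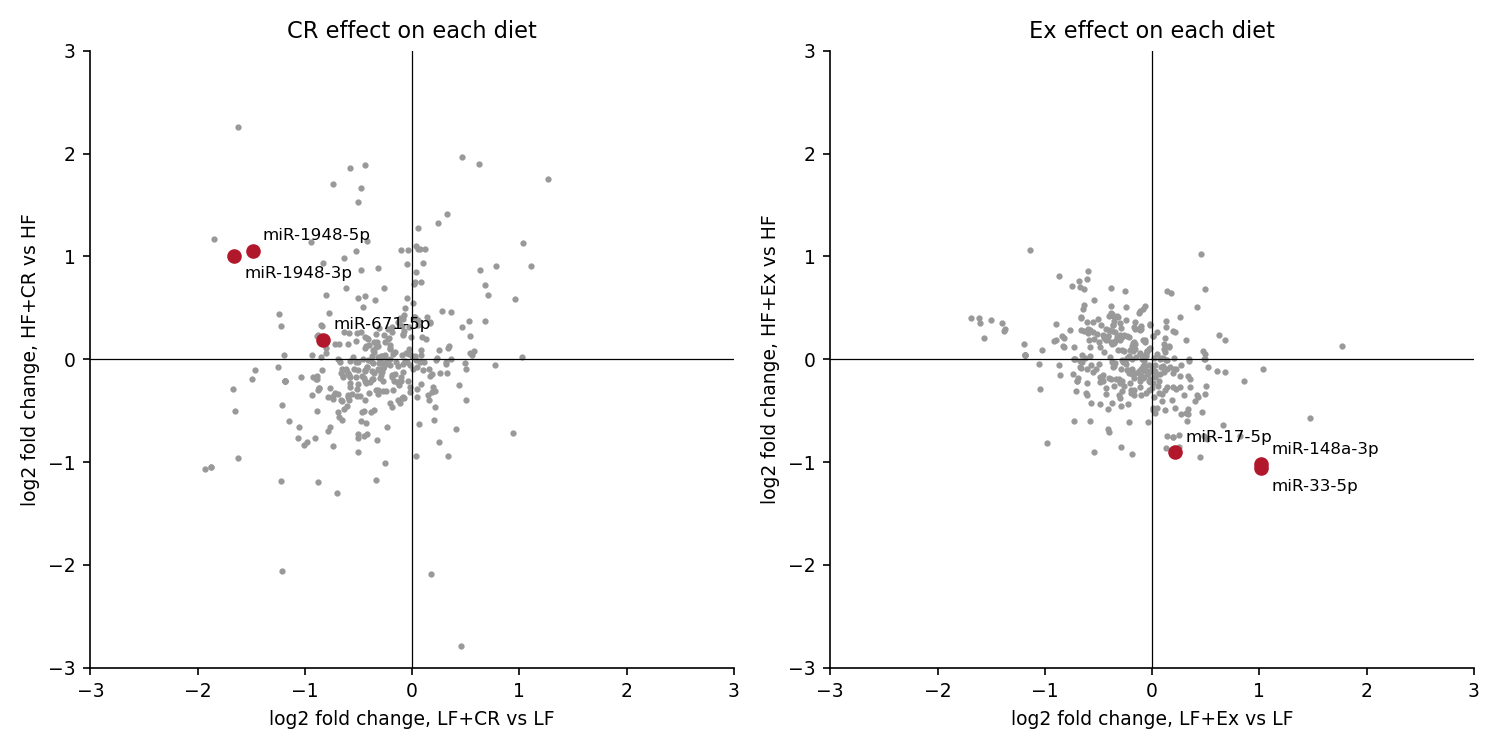
Each point is a tested miRNA, with its log2 fold change on LF on the horizontal axis and on HF on the vertical axis, for CR (left) and Ex (right); red points passed the test of the difference between diets. miR-148a-3p and miR-33-5p lie at 1.02 on LF for Ex and at -1.02 and -1.05 on HF.

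The Ex effect differed between diets for 3 miRNAs, all with a lower value on HF: miR-33-5p (-2.07, SE 0.37, adjusted p = 0.00824), miR-148a-3p (-2.04, SE 0.30, adjusted p = 0.00212) and miR-17-5p (-1.12, SE 0.24, adjusted p = 0.0286). The calls of miR-148a-3p and miR-33-5p held in all of their 24 and 23 alternatives, with adjusted p of 4.91e-04 to 0.0109 and 0.00253 to 0.0379. That of miR-17-5p held in 13 of 24, over a range of 0.00253 to 0.117, and without 1 library only where LF 1 or HF+Ex 1 was left out. miR-33-5p was at 5.14 to 6.35 RPM in LF, near the filter of 5 RPM, and higher in every library of the other groups, HF+Ex included (6.68 to 11.8 RPM). Its calls for the HF diet, for CR on LF and for this difference all use those LF libraries, so they are not separate results. let-7a-5p at 0.83 (adjusted p = 0.0532), miR-20a-5p at -1.10 (adjusted p = 0.0621) and miR-193a-3p at -1.57 (adjusted p = 0.0883) did not pass. Rescaling, which moved the median of all miRNAs by -0.16, gave 8 calls, 1 higher and 7 lower, and kept these 3. Averaged over diets, no miRNA was called for Ex by limma (12 at an unadjusted p under 0.05, where chance gives 17.55; 0 with voom weights). The lowest p values belonged to miR-17-5p at -0.34, miR-592-5p at 0.95, miR-145a-3p at -0.36, miR-1948-3p at 0.43, miR-361-3p at 0.41 and miR-93-5p at -0.33, with an adjusted p of 0.881 each. Camera placed the miR-17/92 clusters lower (median -0.28, 0 of 16 called; adjusted p = 0.0165; adjusted p = 0.948 with an estimated correlation; at most 0.0927 where LF 1, LF+Ex 2 or HF+Ex 2 was left out). The Sfmbt2 cluster had a median of -0.57 (0 of 7 called). Fragment-like entries were placed higher (0.30, 0 of 4 called; adjusted p = 0.0370; adjusted p = 0.948 with an estimated correlation; 0.555 without HF+Ex 1, and also lost without LF 1, LF+Ex 1, LF+Ex 3 or HF 3).

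Other lists had members past the test without passing as lists. For CR on LF, the lipid and sterol list had 1 of 25 higher (miR-33-5p) and 2 lower (miR-27b-3p and miR-128-3p), the obesity and fatty liver list 1 of 23 higher and 1 lower (miR-33-5p and miR-34a-5p), and the miR-34 family 1 of 3 lower. The fibrosis and stellate cell list had 1 of 29 higher and 1 lower (miR-29a-3p and miR-34a-5p), the ageing list 1 of 21 higher and 1 lower (the same pair) and the neuronal list 1 of 7 lower (miR-128-3p). Their camera adjusted p values were 0.764, 0.543, 0.379, 0.517, 0.755 and 0.543. After rescaling the counts were 1 higher and 0 lower for the lipid list (median -0.27 before and 0.07 after), 1 and 1 for the obesity list (-0.26 and 0.08), 0 and 1 for the miR-34 family, 4 and 1 for the fibrosis list (-0.29 and 0.04), 3 and 1 for the ageing list (-0.37 and -0.03) and 0 and 0 for the neuronal list. Adjusted over the list alone, on RPM as deposited, the ageing list had 3 higher and 4 lower and the neuronal list 3 lower. For CR averaged over diets, 3 of 23 of the obesity list (4 adjusted over the list alone), 2 of 21 of the ageing list (6 lower and 1 higher adjusted over the list alone) and 1 of 7 of the neuronal list (miR-137-3p) were lower; after rescaling 1, 1 and 0 were, with 1 higher in the ageing list. Leukocyte and Kupffer cell miRNAs then had a median of -0.70 with 11 of 11 below 0 and 2 lower adjusted over the list alone (camera adjusted p = 0.224), and erythroid miRNAs a median of -0.47 (adjusted p = 0.650). Endothelial miRNAs had a median of -0.10, or 0.10 after rescaling (adjusted p = 0.814), the miR-200 family 0.22 (adjusted p = 0.268) and pancreatic miRNAs 0.50 (adjusted p = 0.540). The muscle list, not tested, had 2 measured members, miR-1a-3p and miR-133a-3p, which summed to between 5.23 RPM (HF 2) and 146 RPM (LF 2).

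Libraries with other cell types' miRNAs stood apart within groups. The acinar pancreas miRNA miR-216a-5p was at 93.9 RPM in LF+CR 1 and 62.5 RPM in HF+CR 1, at 11.01 RPM in LF+Ex 1 and at most 4.17 RPM elsewhere; the islet miRNA miR-375-3p was at 199 RPM in LF+CR 1, 34.7 RPM in LF 3 and 24.1 RPM in HF+CR 1. Neuronal miR-124-3p was at 163 RPM in HF+CR 2 and 46.0 RPM in LF 2, and miR-9-5p at 78.1 and 48.9 RPM in the same libraries. The neuronal-high pair is named for miR-124-3p and miR-9-5p, not for the list. The neuronal list summed to 734 RPM in LF 2, 695 RPM in LF+Ex 3 and 678 RPM in HF+CR 2. Epithelial miR-200b-3p was at 1993 RPM in HF+CR 3 and 1475 RPM in LF 1, and 842 RPM or less elsewhere. The leukocyte list summed to 10130 RPM in HF+CR 3 and 8694 RPM in LF 1; the other LF libraries held 2909 and 4454 RPM and the HF libraries 6715 to 8580 RPM. The fragment-like miR-690 was at 387 RPM in HF+Ex 1, 300 RPM in HF+CR 1 and 110 to 134 RPM in HF 2, HF+CR 2 and HF+CR 3.

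**Figure D4:**
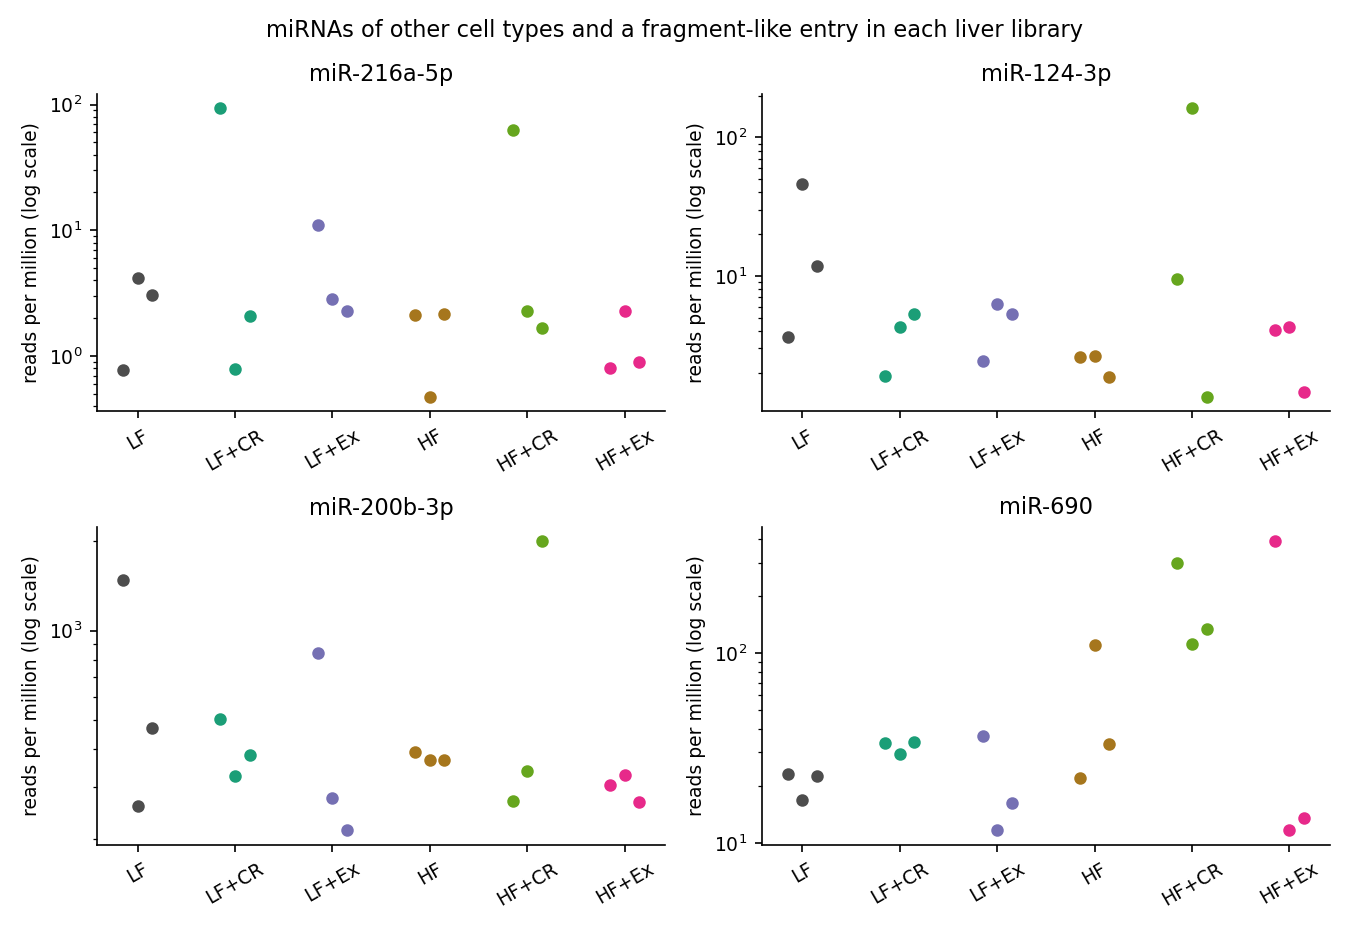
Points are single libraries, by group, on log RPM axes, for a pancreatic (miR-216a-5p), a neuronal (miR-124-3p), an epithelial (miR-200b-3p) and a fragment-like (miR-690) entry. LF+CR 1 and HF+CR 1 stand above the rest for miR-216a-5p, at 93.9 and 62.5 RPM.

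Effects were correlated across the 351 miRNAs, which are not independent replicates; 8 pairs of comparisons were computed, and each value was set against 100 draws of unchanged groups sharing the same libraries. CR effects on LF and on HF had r = 0.21 (simulated mean 0.01; covariance 0.0643 against a simulated 3.94e-04) and the same sign in 60.4% (simulated 50.01%). Ex effects on LF and on HF had r = -0.34 (simulated -0.03; covariance -0.0564 against -0.00344) and the same sign in 39.6%. With a shared control, the HF diet effect and the CR effect on HF had r = -0.56 (simulated -0.45; covariance -0.179 against -0.0723), the HF diet effect and the Ex effect on HF -0.31 (simulated -0.45; covariance -0.0594 against -0.0749). CR and Ex on LF had r = 0.38 (simulated 0.51; covariance 0.0915 against 0.0828). CR and Ex on HF had r = 0.03 (simulated 0.44; covariance 0.00603 against 0.0716), the HF diet and CR on LF 0.09 (simulated 0.49; covariance 0.0241 against 0.0832), and the HF diet and Ex on LF 0.43 (simulated 0.49; covariance 0.108 against 0.0808). None lay outside the simulated spread: between 7 and 86 of the 100 draws were as far from the simulated mean. With 3 control libraries no split leaves 2 in each part, so part of these values may come from the shared controls.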

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

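Tests of library scale, of single libraries and of pancreatic miRNAs below were chosen only after the results they measure were seen. Those of shared reads were built on miRNAs already called, but were set before the family sums were seen. Those of other splits of the samples were set before the counts of the other splits were seen. The miRNAs of the first pattern and the values of the CR effect by diet stood out in a test of whether an effect differed between the LF and HF diets. The direction of change with CR on LF and the pancreatic miRNAs were noticed in the tables and not by that test. Groups of 3 were not tested for single libraries far from the others.

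The Ex effect differed between diets for miR-148a-3p (-2.04), miR-33-5p (-2.07) and miR-17-5p (-1.12). Reads moved between near-identical miRNAs were tested on family sums. The summed miR-148 family still differed by -1.83 (SE 0.27), which argues against it for miR-148a-3p, itself 89.5% of that sum; the miR-17 family sum differed by -0.058 (SE 0.23), which leaves it open for miR-17-5p, as miR-93-5p makes up 74.4% of that sum. For the RPM scale, the value nearest to 0 after rescaling was -1.29 (SE 0.23). Rescaling moved the median of all miRNAs by -0.16, away from 0 for these 3, so this outcome followed from a median already seen and is no separate test. The shift common to all miRNAs thus ran against these 3 differences. A single library is argued against as the whole cause for miR-148a-3p and miR-33-5p, which passed in all 12 omissions (nearest to 0 -1.90, SE 0.39). For miR-17-5p a single library stays open: the value nearest to 0 was -1.003 (SE 0.24, without HF+Ex 3), and the call was kept only without LF 1 (adjusted p = 0.0143) or HF+Ex 1 (0.00253), with up to 0.117 otherwise. A diet-dependent response to Ex may remain for miR-148a-3p and for miR-33-5p, which has no near-identical miRNA among those tested, as a hypothesis found and tested on the same data. For miR-33-5p the LF side rests on LF libraries near the filter, which its calls for the HF diet and for CR on LF share.

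The second pattern was the direction of change with CR on LF, where 20 of 22 called miRNAs were lower. After rescaling 46.7% of the calls were lower, but rescaling centres the median, so this cannot tell the RPM scale from a general decrease. After rescaling 7 of the 20 were still called lower and 20 of 20 lay below 0; the other 13 calls ended with a value nearer to 0 in 13 of 13 (median -0.74 before and -0.41 after) and SE of 0.14 to 0.33 before and 0.15 to 0.38 after, smaller in 7 of 13, so for these the RPM scale cannot be told apart from CR. With each of 6 libraries left out, at least 80.6% (without LF 1, SD over omissions 4.74) of all miRNAs at an unadjusted p under 0.05 were lower. The direction was thus still there without any 1 library. The cut for this share was chosen after the data were seen, and the omissions share libraries, so their SD understates the spread. Without LF 1 the share of all miRNAs below 0 went from 75.2% to 66.1% and the lower calls from 20 to 7. A single library, such as LF 1 or LF+CR 1, thus stays open as part of the cause. The calls rest on single libraries, with 5 left without LF+CR 1 or LF+CR 2 and 9 without LF 1. An effect of CR on these miRNAs was not separated from library composition and may account for part of it.

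The third pattern was the high pancreatic miRNAs of LF+CR 1 and HF+CR 1, which summed to 150 and 114 RPM over the members low elsewhere. Pancreas tissue carried along with the liver stays open: 3 of the 10 listed members (miR-216a-5p, miR-216b-5p and miR-217-5p) had these as their 2 highest libraries, but these 3 are neighbours in the genome and are the ones that drew notice. The islet miRNA miR-375-3p followed in part: it was at 199 RPM in LF+CR 1, 34.7 RPM in LF 3 and 24.1 RPM in HF+CR 1, and at most 9.51 RPM elsewhere. miR-7b-5p did not follow, with its highest value in LF 3 (5.35 RPM). Over the 4 tested members the count was 1, but these include the miR-7a forms, high in every library (miR-7a-5p at a mean of 877 RPM in the other 16), so this count decides little. CR itself stays open: 0 of the other 4 CR libraries exceeded the highest library without CR (18.8 RPM; highest of the 4, 5.12 RPM), but the members were picked for low values in those libraries too, so this count decides nothing.

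The CR effect differed between diets for miR-1948-3p (2.67), miR-1948-5p (2.54) and miR-671-5p (1.02). List medians with a camera call for the same difference were -0.22 for hepatocyte-enriched miRNAs, 0.040 for the insulin and glucose list, -0.37 for the miR-29 family and 1.29 for the Dlk1-Dio3 cluster. None of these calls held in camera with an estimated correlation (adjusted p = 0.769, 0.675, 0.642 and 0.966, in the same order). Rescaling turned the insulin and glucose median to -0.22.

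Other splits of the samples gave the following counts of called miRNAs. For comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05: HF against LF had 1 in the real split and 0 in the highest other (1 split with as many), and LF+CR against LF 22 and 1 (1 split). LF+Ex against LF had 0 and 0 (10 splits), HF+CR against HF 0 and 0 (10 splits) and HF+Ex against HF 3 and 0 (1 split). With 100 splits drawn within each diet, CR averaged over diets had 23 against at most 3 in the others and Ex by diet 3 against at most 1. Each was reached by 1 split, the real one. This argues against chance alone for these counts but does not exclude it, since 1 of 100 is the smallest share such a draw can give. The shares were not adjusted over the comparisons. CR by diet had 3 against 44 in the highest other, with 6 splits as large, so this count does not exclude chance. Nor does it stand for unchanged groups: 4 of the 6 exchanged all LF with all LF+CR libraries, and in 3 of these most HF+CR libraries kept their place, which turns the difference between diets towards an average over diets, where CR had 23 calls. Of the 77 other splits that divided the groups on both diets, 1 called as many (10). Ex averaged had 0 against 6 in the highest other; as the real count is 0, all 100 splits reach it and the comparison says nothing, as for LF+Ex and HF+CR. The split with 44 calls is 1 of these 3, and also exchanged HF 1 with HF+CR 3, so the structure of the samples it points to holds the averaged effect of CR.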

How the results depend on the processing

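Fits without an intensity trend, with voom weights, with identical miRNAs counted once, and with sets of libraries left out were chosen after the data were seen. Among 87 named pairs of miRNA and comparison, 37 of them past the test, 1733 alternative values had 1453 on the same side of the threshold, 227 weaker, 53 stronger and 0 in the opposite direction. Counts of calls moved by over 1.5 times as follows; the cause was not tested. With RPM of at least 50: HF against LF 0. With median-of-ratios rescaling: HF against LF 2, LF+Ex against LF 1, HF+Ex against HF 1, CR averaged 8, CR by diet 1 and Ex by diet 8. With only the compared groups in the fit: HF against LF 0, LF+CR against LF 0, HF+Ex against HF 1, CR averaged 0, CR by diet 1 and Ex by diet 12. With no filter: HF+Ex against HF 1 and Ex by diet 5. With no intensity trend: HF+Ex against HF 1. With voom weights on reads: LF+Ex against LF 1. With high pancreatic miRNAs left out (LF+CR 1, HF+CR 1): LF+CR against LF 5, CR averaged 0 and CR by diet 1. With high neuronal miRNAs left out (LF 2, HF+CR 2): HF against LF 0, LF+CR against LF 55, CR averaged 12, CR by diet 17 and Ex by diet 6. With high leukocyte and epithelial miRNAs left out (LF 1, HF+CR 3): HF against LF 7, HF+CR against HF 25, CR averaged 63, CR by diet 6 and Ex by diet 6. With the 3 shallowest left out (HF+CR 1, HF+CR 3, HF+Ex 1): HF+CR against HF 9, CR averaged 49, CR by diet 6 and Ex by diet 5. Over the 189 list tests camera made 23 calls; with an estimated correlation 0 were made and by directional fry 0, while mixed fry, which asks for change in either direction, made 28.

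With 1 library left out, counts ranged from 0 to 2 for HF against LF, 5 to 40 for LF+CR against LF and 0 to 2 for LF+Ex against LF. They ranged from 0 to 22 for HF+CR against HF, 0 to 5 for HF+Ex against HF, 0 to 78 for CR averaged, 1 to 9 for CR by diet, 2 to 4 for Ex by diet and 14 (without LF 1) to 26 for lists. Ex averaged had 0 by limma in each, with 12 at an unadjusted p under 0.05 over all libraries. Depths of 2.38 to 10.5 M reads per library limited low miRNAs, since a listed value stood for at least 2 reads.

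With the replicate number as a block, LF+CR against LF had 24 calls, HF+Ex against HF 2, CR averaged 22, CR by diet 2 and lists 22, and other counts did not change. The libraries share only a number: 14 of 45 pairs with the same number had r over 0.1 after removing group means, the mean r was 0.0287 against -0.0139 for different numbers, and 7 of 18 libraries correlated best with their own number. The count-model alternatives set earlier were not run, as a listed 0 can stand for 1 read.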
